A study of Mus musculus with 13 samples.

How the data were processed

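The study measured RNA in epididymal white adipose tissue, a visceral fat depot of male mice, on 13 Affymetrix arrays, from 100 ng of total RNA each. The groups, taken from the labels, were wild-type mice (C57BL/6) on low-fat chow, wild-type mice on high-fat diet and P2X7 knockout mice (B6.129P2-P2rx7tm1Gab/J, backcrossed for 7 generations) on chow, with 3 arrays each, and knockout mice on high-fat diet, with 4 arrays. The labels do not state that each array held 1 animal, so the p-values measure the spread between these samples.

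The deposited values are log2 expression values, 1 per probe set and array, normalised by the authors with RMA (robust multi-array averaging), per the submitters' processing notes; the RMA version is not given in the sources used here. They ran from 1.70 to 13.86 over 35556 probe sets. No further normalisation was applied. Of the probe sets, 21218 were paired with 1 gene symbol in the platform's annotation, 1881 with several and 12457 with none, and only those paired with 1 gene were named and tested. Where a gene had several, the probe set with the highest mean over all arrays stood for it, which gave 18820 genes. Of these, 18790 matched the RefSeq gene table of the GRCm38.p6 assembly by Entrez ID, and 0 names changed. That table was used for names and gene order only, because the build behind the array annotation is not given in the sources used here.

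Genes were tested with limma 3.58.1 in R 4.3.3 with version 1.17.8 of the data.table package. One linear model with a mean for each of the 4 groups was fitted to all 13 arrays, and variances were moderated with an intensity trend. Contrasts gave the effect of diet in each genotype, of genotype on each diet and averaged over the diets, and the diet-by-genotype interaction. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. A plus-minus sign after a log2 change gives its standard error (SE) from limma. The 21 gene lists and 17 cell-type marker lists held 610 entries, of which 63 were not measured and 4 matched through a synonym. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the 38 lists. Camera with a correlation estimated from the arrays and fry were run beside it. Members of each list were also adjusted over the list alone. Single values were compared by exact permutation, two-sided, and counts of genes beside P2rx7 by Fisher's exact test with its 95% confidence interval. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

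The groups, contrasts, tests, lists and named genes were fixed before the data were examined. P2rx7 came first, and Nlrp3, Pycard, Casp1, Il1b and Il18 were always given. The rule further named the 8 largest rises and 8 largest falls among genes that passed and whose groups did not overlap, leaving out predicted genes, small RNAs and clone names. From each list it allowed up to 4 passing members with the smallest p, or 2 as values where none passed. For genotype it allowed up to 8 passing genes within 100 measured genes of P2rx7. A430033K04Rik, the clock genes other than Ciart, and Alb lie outside the rule and were chosen after their values were seen, and the clock and liver lists were written then.

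The steps were tested on simulated arrays with the spread of the real ones, in which 200 of 18820 genes were changed by 1.5-fold or 2-fold. The share of changed genes recovered, at 1.5-fold and at 2-fold, was 70% and 95% for diet in wild-type mice, 82% and 97% for diet in knockout mice, 68% and 92% for genotype on chow, 74% and 96% for genotype on high-fat diet, 92% and 99% for genotype over both diets, and 52% and 84% for the interaction. Unchanged genes made up 6.1%, 7.1%, 4.7%, 2.8%, 5.2% and 6.2% of the calls, in the same order of comparisons. The simulated genes varied independently of each other and 200 of them changed, so the shares recovered may be too high for comparisons with few real changes. The number of arrays limits the precision. Alternatives changed the variance model, scaling, filter on dim genes, probe sets per gene, array weights, groups in the fit, minimum fold change, list test, distance to P2rx7 and replicate block, and left out each array in turn. A liver score as covariate and the removal of 2 arrays together were added after seeing the data. Probe sets with no gene or several genes were left out of the tests of genes, since they cannot be named.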

Results

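Arrays measured gene expression in epididymal white adipose tissue of 18-week-old male mice that had eaten low-fat chow (13% of energy from fat) or a high-fat diet (60%) for 12 weeks. Wild-type mice on chow, wild-type mice on high-fat diet and P2X7 knockout mice on chow had 3 arrays each, and knockout mice on high-fat diet had 4. P2X7 is a channel opened by extracellular ATP and known to trigger the NLRP3 inflammasome, the protein complex that activates caspase-1, and the design asks whether it matters for inflammasome genes in obese fat. The median log2 value per array lay between 5.72 and 5.88 over all probe sets, and arrays of 1 group correlated at r of 0.993 to 0.998 across the genes tested. The first principal component held 74.7% of the variance and separated the diets, with chow arrays from -46.1 to -32.6 and high-fat arrays from 23.0 to 41.8.

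P2rx7, the targeted gene (Entrez 18439), was read by 1 probe set whose place relative to the altered part of the gene is not given in the sources used here, so its level checks nothing about the genotype labels. The P2rx7 log2 values on chow were 8.32, 7.91 and 8.41 in wild-type mice and 8.23, 7.90 and 8.04 in knockout mice. On high-fat diet P2rx7 read 9.54, 9.36 and 9.70 in wild-type mice and 8.90, 9.14, 9.14 and 9.07 in knockout mice. P2rx7 rose with the diet by 1.32 ± 0.13 in wild-type mice (limma adjusted p 3.92e-06) and by 1.01 ± 0.12 in knockout mice (adjusted p 3.04e-05). The genotype difference of P2rx7 was -0.16 ± 0.13 on chow (adjusted p 0.741) and -0.47 ± 0.12 on high-fat diet (adjusted p 0.464), neither past the threshold, although on high-fat diet every P2rx7 value of knockout mice lay below every value of wild-type mice.

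**Figure D1:**
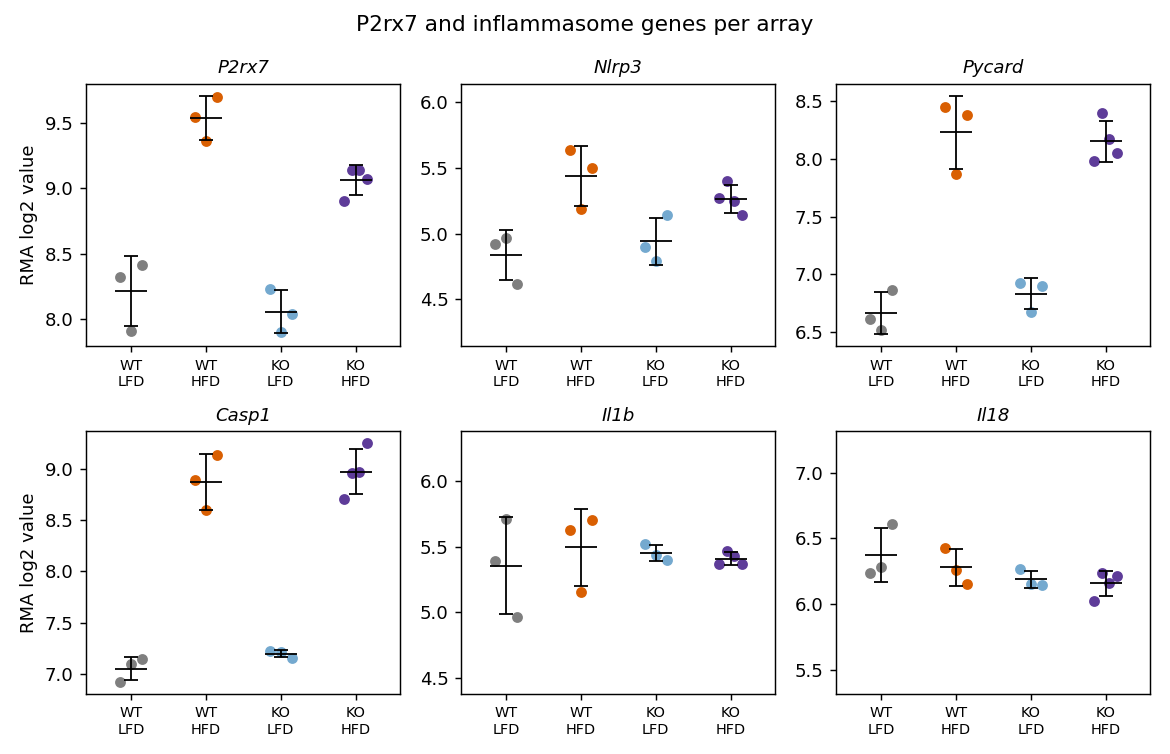
Log2 expression of P2rx7 and 5 inflammasome genes on each array by group, with group means and SD. P2rx7, Pycard and Casp1 lie higher on high-fat diet in both genotypes, while Il1b and Il18 do not separate by diet.

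In wild-type mice, the effect of diet was asked first for the inflammasome. The arrays read whole tissue, in which most macrophage genes rose too, as given below. For P2rx7, inflammasome and purinergic genes, more RNA per cell and a larger share of macrophages cannot be told apart, in either genotype. Casp1, which encodes caspase-1, rose by 1.82 ± 0.14 (limma adjusted p 4.18e-07), Pycard, the adaptor ASC, by 1.57 ± 0.15 (adjusted p 3.46e-06) and Nlrp3 by 0.61 ± 0.13 (adjusted p 0.00294). Their cytokine substrates did not pass, with Il1b at 0.14 ± 0.17 (adjusted p 0.575) and Il18 at -0.10 ± 0.11 (adjusted p 0.552). Over all arrays Il1b read 4.97 to 5.71 and Nlrp3 4.62 to 5.63, below the array medians over genes (6.56 to 6.69). Signal over background was not used for them. Il1rn, the IL-1 receptor antagonist, rose by 3.49 ± 0.26, and Nlrc4, another inflammasome sensor, by 1.96 ± 0.17. Of 22 measured genes of the inflammasome and IL-1 family, 13 rose and 1 fell, with a median log2 change of 0.61 (camera adjusted p 8.79e-05, and 0.343 with the correlation between genes estimated). Among 18 purinergic receptors and ectonucleotidases, 7 rose and 4 fell (5 fell when adjusted over the list alone). P2rx4, the P2X channel closest to P2X7, rose by 1.42 ± 0.09, the UDP receptor P2ry6 by 2.01 ± 0.14, the ATP-degrading Entpd1 (CD39) by 0.92 ± 0.10 and the ATP-release channel Panx1 by 1.43 ± 0.17. The purinergic median was -0.01 and the mean 0.19, and camera, pointing up, did not pass (adjusted p 0.28), while fry did (adjusted p 0.000717). With a liver score as covariate, added after seeing the data, Nlrp3 stood at 0.53 ± 0.20 and did not pass (adjusted p 0.0862), because its SE widened.

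Across all 18820 genes, 3327 rose and 3409 fell with the diet in wild-type mice, of which 1648 rose and 1379 fell at least 1.5-fold. The balance depends on scaling: 2874 rose and 4352 fell with arrays centred on their medians, and 3135 and 3850 after a second quantile normalization. The largest rise was that of Gpr50, an orphan receptor, by 6.09 ± 0.51 (68.3-fold). It was followed by Tm4sf19 (5.68 ± 0.37) and by Atp6v0d2, a proton-pump subunit of macrophages and osteoclasts (5.51 ± 0.46). Rgs1 rose by 5.39 ± 0.38, the ubiquitin ligase Rnf128 by 5.36 ± 0.34, the choline transporter Slc5a7 by 4.62 ± 0.36 and the serotonin receptor Htr2b by 4.60 ± 0.23. Serpinb9b also rose (4.78 ± 0.57), though its probe set may read near-identical copies. The largest falls were those of the sialyltransferase St6galnac5 (-3.71 ± 0.25, 13.1-fold), the acute-phase gene Orm3 (-3.52 ± 0.25), again with close copies, and Fam13a (-3.39 ± 0.16). Cyp2f2 (-3.38 ± 0.31), Acsm5 (-2.99 ± 0.18), Mogat1, a monoacylglycerol acyltransferase (-2.98 ± 0.23), and Ankef1 (-2.89 ± 0.16) fell too. Cyp2e1, abundant in liver as well as in fat, fell by 3.07 ± 0.54.

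Macrophage genes rose in wild-type mice: Adgre1 (F4/80) by 2.32 ± 0.13, Cd68 by 2.29 ± 0.14 and Ms4a7 by 3.09 ± 0.18. In that list 18 of 19 genes rose and 1 fell (median 1.32, camera adjusted p 5.67e-13, and 0.227 with estimated correlation). Of 19 genes of lipid-associated macrophages, 15 rose and 2 fell (median 1.86, adjusted p 4.58e-10, and 0.159 with estimated correlation), with the lipid receptor Trem2 up by 3.89 ± 0.22, the lipid-droplet coat Plin2 by 1.18 ± 0.06 and the lysosomal lipase Lipa by 2.13 ± 0.14. Lysosomal genes rose in 18 of 19 cases and fell in 0 (median 0.76, adjusted p 1.21e-12, and 0.159 with estimated correlation), led by Gla (2.52 ± 0.13) and Ctsz (1.00 ± 0.06). Of 23 chemokines and cytokines, 14 rose and 1 fell, or 16 and 1 when adjusted over the list alone (median 0.73, adjusted p 1.08e-05, and 0.159 with estimated correlation). Ccl3 rose by 3.63 ± 0.28, Tnf by 2.15 ± 0.19 and Tgfb1 by 1.19 ± 0.11. Of 11 genes of MHC class II presentation, 8 rose and 0 fell (median 0.41, adjusted p 0.000578, and 0.479 with estimated correlation), among them Ctss (2.66 ± 0.22) and the class II transactivator Ciita (1.01 ± 0.14). Interferon-stimulated genes did not pass by camera (2 rose and 1 fell of 20, median 0.19, adjusted p 0.223), with Oasl1 up by 1.82 ± 0.18, Oas1a up by 1.52 ± 0.17 and Gbp2 at -0.58 ± 0.17. Gbp2 did not pass without replicate 1 of wild-type mice on chow or replicate 1 on high-fat diet, with values across the arrays left out from -0.67 to -0.47.

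Adipocyte genes fell in wild-type mice. Slc2a4, the insulin-responsive glucose transporter GLUT4 (-2.31 ± 0.21), Pck1, needed for glycerol synthesis (-2.39 ± 0.15), the insulin receptor substrate Irs1 (-1.58 ± 0.12) and resistin (Retn, -1.23 ± 0.12) were among them. Of 19 adipocyte identity genes 0 rose and 16 fell (median -0.73, camera adjusted p 1.39e-08, and 0.475 with estimated correlation). Breakdown of branched-chain amino acids fell in 18 of 19 genes, or 19 when adjusted over the list alone (median -1.16, adjusted p 7.56e-13, and 0.227 with estimated correlation), with Ivd down by -1.67 ± 0.13, Bcat2 by -1.16 ± 0.09, Acadsb by -1.43 ± 0.11 and Hsd17b10 by -0.91 ± 0.06. Oxidative phosphorylation fell in 17 of 25 genes, or 21 when adjusted over the list alone (median -0.24, adjusted p 1.55e-05, and 0.498 with estimated correlation), among them Ndufb8 (-0.79 ± 0.08) and Sdhb (-0.54 ± 0.07). In de novo lipogenesis 1 rose and 12 fell of 21 (median -0.55, adjusted p 0.00206, and 0.532 with estimated correlation). The acetyl-CoA carboxylases Acaca (-1.84 ± 0.24) and Acacb (-1.82 ± 0.19) fell with their regulator Mlxipl (ChREBP, -1.41 ± 0.15), while the elongase Elovl3 rose by 2.20 ± 0.39. Cholesterol synthesis went the other way, with 10 risen and 1 fallen of 18 (median 0.62, adjusted p 0.000526, and 0.479 with estimated correlation), and with Dhcr7 up by 1.47 ± 0.13, Msmo1 up by 0.93 ± 0.15 and Fdft1 at -0.85 ± 0.15.

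Camera did not pass the other metabolic lists, while fry passed glutathione and oxidant defence (adjusted p 5.59e-05) and adipose expansion (adjusted p 0.00415). Fatty acid oxidation had 2 risen and 10 fallen of 19 (median -0.30, camera adjusted p 0.0529), with the nuclear receptor Ppara at -1.12 ± 0.19, its coactivator Ppargc1a at -1.14 ± 0.20 and the carnitine transferase Cpt1a at 0.47 ± 0.07. Glutathione and oxidant defence had 5 risen and 11 fallen of 21, or 12 fallen when adjusted over the list alone (median -0.36, adjusted p 0.072), and the glutathione transferases Gsta4 (-2.69 ± 0.17) and Gsta3 (-2.22 ± 0.13) fell while haem oxygenase (Hmox1) rose by 2.04 ± 0.16. Glycolysis and hypoxia had 7 risen and 4 fallen of 18, or 8 and 4 when adjusted over the list alone (adjusted p 0.485), with Car9 at 1.65 ± 0.16 and Ndrg1 at -1.04 ± 0.09. Adipose expansion had 3 risen and 9 fallen of 17 (adjusted p 0.215), with angiotensinogen (Agt) at -2.75 ± 0.13 and Gpr176 at 2.21 ± 0.18. Thermogenic genes had 5 risen and 1 fallen of 14 (adjusted p 0.243), and Otop1 rose by 3.32 ± 0.25.

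Dividing cells and matrix left a clear trace in wild-type mice. All 18 measured cell division genes rose (median 1.99, camera adjusted p 8.38e-18, and 0.165 with estimated correlation), with the mitotic kinase Bub1 up by 2.94 ± 0.17, Cdk1 by 2.29 ± 0.15, Ccnb2 by 2.31 ± 0.13 and Ccna2 by 2.28 ± 0.13. Among 26 collagens and matrix genes 19 rose and 1 fell, or 21 and 1 when adjusted over the list alone (median 0.62, adjusted p 3.21e-08, and 0.165 with estimated correlation). Col6a3 rose by 1.08 ± 0.08, Postn by 1.40 ± 0.11, Lum by 1.47 ± 0.13 and the protease Mmp3 by 3.49 ± 0.34. The unfolded protein response had 10 risen and 3 fallen of 16 (median 0.30, adjusted p 0.0433, and 0.479 with estimated correlation), where Atf3 rose by 3.43 ± 0.16, the chaperone partner Sdf2l1 by 1.34 ± 0.18 and asparagine synthetase (Asns) stood at -1.28 ± 0.09. Mast cell genes rose in 5 of 9 cases, or 6 when adjusted over the list alone (median 1.25, adjusted p 0.0281, and 0.566 with estimated correlation). The mast cell proteases Cma1 (1.36 ± 0.38) and Cpa3 (1.57 ± 0.45) did not pass without replicate 3 of wild-type mice on high-fat diet, nor did Cpa3 without replicate 2 on chow, and they ranged from 0.94 to 1.84 and from 1.07 to 2.18 across the arrays left out.

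Markers of other cells fell in wild-type mice. Of 9 mesothelial genes 7 fell, or 8 when adjusted over the list alone (median -1.14, camera adjusted p 0.00196, and 0.504 with estimated correlation), including Wt1 (-0.99 ± 0.16), Upk1b (-1.50 ± 0.27) and Upk3b (-1.47 ± 0.30). Smooth muscle and pericyte genes fell in 8 of 10 cases, or 9 when adjusted over the list alone (median -0.70, adjusted p 0.00267, and 0.479 with estimated correlation), with Rgs5 at -1.06 ± 0.14 and Tagln at -0.69 ± 0.14. Endothelial genes fell in 7 of 11 cases (median -0.44, adjusted p 0.00824, and 0.532 with estimated correlation), with the VEGF receptor Kdr at -0.77 ± 0.19 and Robo4 at -0.81 ± 0.15. No camera test passed for neutrophils (2 rose and 2 fell of 9, adjusted p 0.928, median 0.01 and mean -0.06), although Csf3r rose by 1.20 ± 0.11 and Elane stood at -1.09 ± 0.10. Nor did one pass for dendritic cells (4 rose and 3 fell of 8, 5 rising when adjusted over the list alone, adjusted p 0.285), fibroblasts (2 and 4 of 10, adjusted p 0.648), T cells (1 and 0 of 8, adjusted p 0.485), B cells (0 and 0 of 11, adjusted p 0.486) or natural killer cells (1 and 0 of 8, 0 when adjusted over the list alone, adjusted p 0.612). The same held for eosinophils (0 and 1 of 5, adjusted p 0.554), skeletal muscle (1 and 2 of 11, median 0.01, mean 0.02 and camera pointing down, adjusted p 0.728), with Pvalb up by 2.94 ± 0.24, red blood cells (0 and 2 of 3, adjusted p 0.169) and Schwann cells (0 and 1 of 6, adjusted p 0.648). Lymphatic endothelium (0 and 2 of 5, 3 falling when adjusted over the list alone, adjusted p 0.271), with Lyve1 at -1.06 ± 0.24, epididymis (0 and 1 of 12, 0 when adjusted over the list alone, adjusted p 0.28) and testis (0 and 0 of 10, adjusted p 0.486) did not pass either. For the lists described, list-alone counts are given only where they differ from those over all genes. Camera passed 11 lists upward and 7 downward, and with an estimated correlation it passed 0, the smallest adjusted p being 0.159. Fry passed 25, not mast cells (adjusted p 0.0792) but also dendritic cells (adjusted p 0.00415), lymphatic endothelium (adjusted p 0.00109), epididymis (adjusted p 0.0117), red blood cells (adjusted p 0.0317) and Schwann cells (adjusted p 0.0461).

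A mean over liver transcripts, a list written after the data were seen, stood in wild-type mice at 6.99 ± 0.38 on chow (SD, n = 3) and at 5.89 ± 0.67 on high-fat diet (SD, n = 3; exact two-sided p 0.1, the smallest these numbers allow). The score did not overlap between the diets in wild-type mice (6.68 to 7.42 on chow, 5.30 to 6.62 on high-fat diet). A fit with it as covariate therefore separates diet from the score poorly. With this score as covariate, 1996 genes rose and 1689 fell with the diet. Of 94 genes named here as changed in wild-type mice, 82 passed with it. Of the 12 that did not, Cyp2e1 (-1.53 ± 0.53) is itself part of the score, so its loss decides little. In knockout mice Cyp2e1 passed with the covariate (-3.02 ± 0.36). Lyve1 (-1.07 ± 0.37), Tagln (-0.59 ± 0.20) and Nlrp3 moved by less than their SE and failed because the SE widened. Cma1 (0.30 ± 0.38), Cpa3 (0.32 ± 0.46), Gbp2 (-0.33 ± 0.24), Kdr (-0.39 ± 0.24), Robo4 (-0.53 ± 0.19), Ppara (-0.70 ± 0.23), Upk1b (-1.01 ± 0.35) and Upk3b (-0.92 ± 0.40) shrank by more than 1 SE.

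**Figure D2:**
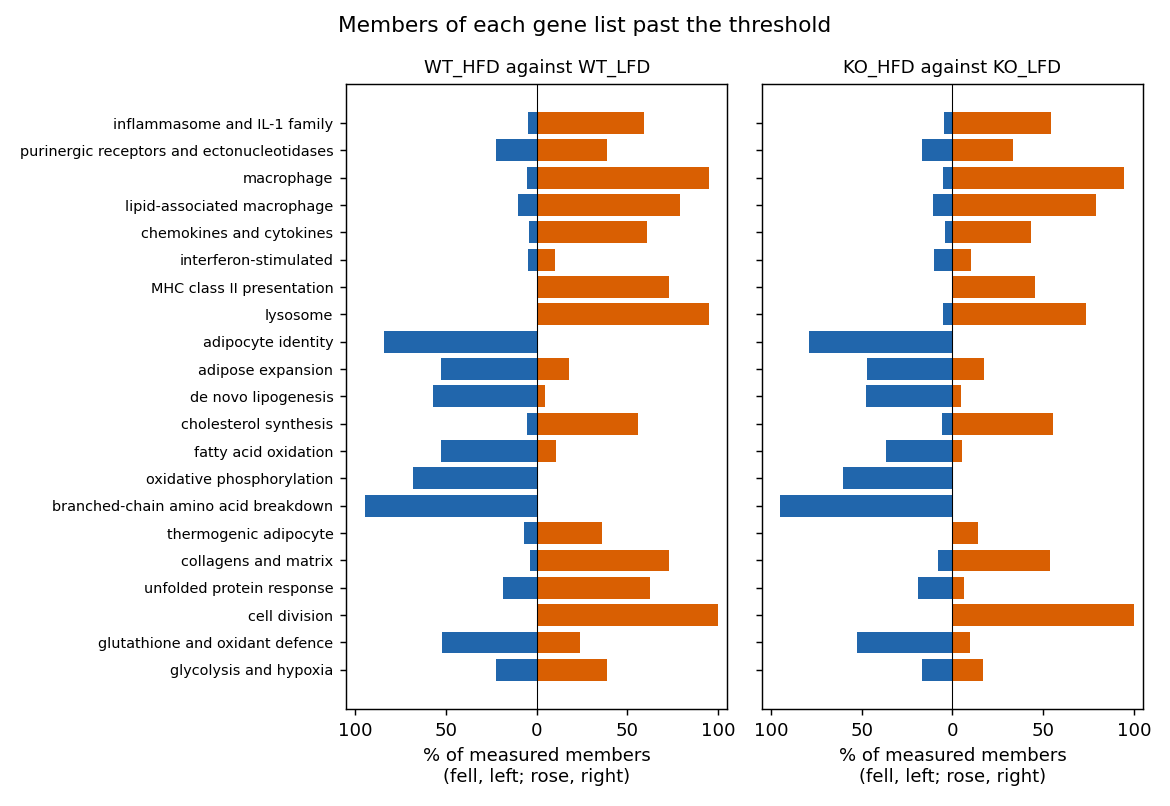
Percent of the measured members of each gene list that rose (right) or fell (left) past the threshold by diet in wild-type and in knockout mice. In both genotypes most macrophage, lysosome and cell division genes rose, and most genes of adipocyte identity and branched-chain amino acid breakdown fell.

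The same diet was asked about in knockout mice. Casp1 rose by 1.78 ± 0.13 (limma adjusted p 4.37e-07) and Pycard by 1.32 ± 0.14 (adjusted p 1.11e-05), whereas Nlrp3, at 0.32 ± 0.13 (adjusted p 0.0641), did not pass. Nlrp3 passed without replicate 3 of knockout mice on chow (0.42, adjusted p 0.0337) and without replicate 2 of wild-type mice on high-fat diet, an array that enters only the estimate of the spread (adjusted p 0.0382). It also passed with array weights (adjusted p 0.0258) and with only the groups compared in the fit (adjusted p 0.0339), so this call depends on the model. The diet effect on Nlrp3 was not shown to differ between the genotypes (interaction -0.28 ± 0.18, adjusted p 0.639). Il1b stood at -0.04 ± 0.16 (adjusted p 0.869) and Il18 at -0.03 ± 0.10 (adjusted p 0.859). Il1rn rose by 2.67 ± 0.25 and the DNA sensor Aim2 by 1.37 ± 0.14. In the inflammasome list 12 rose and 1 fell of 22, or 13 and 1 when adjusted over the list alone (median 0.51, camera adjusted p 4.88e-06, and 0.221 with estimated correlation). Purinergic genes had 6 risen and 3 fallen of 18 (adjusted p 0.0981, and 0.00109 by fry), with P2rx4 up by 0.84 ± 0.09, P2ry6 by 1.78 ± 0.13, Entpd1 by 0.67 ± 0.10 and the UDP-glucose receptor P2ry14 by 1.17 ± 0.15.

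In all, 2721 genes rose and 3708 fell with the diet in knockout mice, of which 1335 rose and 1139 fell at least 1.5-fold. Gpr50 again rose most (5.77 ± 0.48), followed by Tm4sf19 (4.11 ± 0.35), Cd72 (3.94 ± 0.26), Htr2b (3.92 ± 0.22), Rgs1 (3.91 ± 0.35), Rnf128 (3.90 ± 0.32) and the cadherin Fat3 (3.90 ± 0.24). The olfactory receptor Olfr111 rose by 3.87 ± 0.29, though its large family has close copies. The largest falls were those of Orm3 (-3.70 ± 0.24), Cyp2e1 (-3.50 ± 0.50), Cyp2f2 (-3.36 ± 0.29), Fam13a (-3.16 ± 0.15), Mogat1 (-2.83 ± 0.22), Acsm5 (-2.75 ± 0.16) and Asb12 (-2.71 ± 0.23). Rnase2a, an eosinophil ribonuclease with close copies, fell by 3.09 ± 1.04 (adjusted p 0.0341), but it passed in only 6 of 13 fits that left out 1 array, failing without each one of the 7 arrays of knockout mice.

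Immune lists rose in knockout mice as well. Of 19 macrophage genes 18 rose and 1 fell (median 1.22, camera adjusted p 8.95e-15, and 0.188 with estimated correlation), with Adgre1 up by 1.95 ± 0.13, Cd68 by 1.95 ± 0.13 and Ms4a7 by 2.72 ± 0.17. Lipid-associated macrophage genes had 15 risen and 2 fallen of 19 (median 1.72, adjusted p 7.5e-10, and 0.119 with estimated correlation), with Trem2 up by 3.26 ± 0.21, Plin2 by 0.85 ± 0.06 and Lipa by 1.79 ± 0.13. Lysosomal genes had 14 risen and 1 fallen of 19, or 16 and 1 when adjusted over the list alone (median 0.47, adjusted p 2.6e-11, and 0.119 with estimated correlation), with Gla at 1.98 ± 0.13. Chemokines and cytokines had 10 risen and 1 fallen of 23 (median 0.47, adjusted p 1.96e-05, and 0.119 with estimated correlation), among them Ccl3 (2.67 ± 0.26), Tgfb1 (1.01 ± 0.11) and Il10 (1.26 ± 0.16). MHC class II genes had 5 risen of 11 (median 0.28, adjusted p 0.001, and 0.48 with estimated correlation), with Ciita at 0.59 ± 0.13 and H2-Aa at 0.33 ± 0.09, the latter not past the threshold without replicate 2 of knockout mice on chow (largest adjusted p 0.066). Mast cell genes had 7 risen of 9 (median 1.28, adjusted p 0.00332, and 0.604 with estimated correlation), with Mcpt4 at 1.83 ± 0.45. Interferon-stimulated genes had 2 risen and 2 fallen of 20 (median -0.18, adjusted p 0.77), and Oasl1 rose by 0.98 ± 0.17. Of 11 B cell genes 2 rose (adjusted p 0.142), namely Igkc by 2.52 ± 0.49 and Ighm by 1.39 ± 0.45. Without replicate 2 of knockout mice on high-fat diet, where Ighm read 8.725 against 6.56 to 6.57 on the other 3, Igkc stood at 2.17 ± 0.46 and Ighm at 0.85 ± 0.23, both past the threshold, and the list median went from 0.21 to -0.05. Ighm did not pass without replicate 2 or replicate 3 of knockout mice on chow, and its value ranged from 0.85 to 1.62 over the arrays left out.

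Adipocyte identity had 0 risen and 15 fallen of 19 in knockout mice, or 16 fallen when adjusted over the list alone (median -0.66, camera adjusted p 2.84e-07, and 0.48 with estimated correlation), with Slc2a4 down by -2.25 ± 0.20, Pck1 by -2.42 ± 0.14 and Irs1 by -1.46 ± 0.11. Branched-chain amino acid breakdown had 18 fallen of 19 (median -0.93, adjusted p 1.85e-11, and 0.221 with estimated correlation), with Ivd at -1.70 ± 0.12. Oxidative phosphorylation had 15 fallen of 25, or 16 when adjusted over the list alone (median -0.20, adjusted p 0.000319, and 0.63 with estimated correlation), with Ndufb8 at -0.69 ± 0.08. De novo lipogenesis had 1 risen and 10 fallen of 21 (median -0.37, adjusted p 0.0379, and 0.806 with estimated correlation), with Thrsp at -1.88 ± 0.25, Acacb at -1.32 ± 0.18 and Elovl3 at 2.78 ± 0.36. Cholesterol synthesis had 10 risen and 1 fallen of 18, or 14 and 1 when adjusted over the list alone (median 0.46, adjusted p 0.000319, and 0.48 with estimated correlation), with Dhcr7 at 1.35 ± 0.12. Glutathione and oxidant defence had 2 risen and 11 fallen of 21, or 3 and 11 when adjusted over the list alone (median -0.29, adjusted p 0.0379, and 0.221 with estimated correlation), with Gsta4 at -2.54 ± 0.16. All 18 cell division genes rose (median 1.76, adjusted p 3.44e-21, and 0.119 with estimated correlation), with Cdk1 up by 2.35 ± 0.14. Collagens and matrix had 14 risen and 2 fallen of 26, or 16 and 2 when adjusted over the list alone (median 0.65, adjusted p 1.66e-08, and 0.119 with estimated correlation), with Lum at 1.70 ± 0.12. All 9 mesothelial genes fell (median -1.15, adjusted p 0.00299, and 0.604 with estimated correlation), with Krt19 at -1.62 ± 0.31. Camera passed 10 lists upward and 6 downward, 0 of them with an estimated correlation (smallest adjusted p 0.119). Fry passed 18, not mast cells (adjusted p 0.052).

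Some lists that passed in wild-type mice did not pass in knockout mice. The unfolded protein response had 1 risen and 3 fallen of 16 (median 0.02, camera adjusted p 0.756), with Atf3 up by 2.47 ± 0.15 and Xbp1 at -0.49 ± 0.07. Smooth muscle and pericyte genes had 1 risen and 2 fallen of 10, or 1 and 1 when adjusted over the list alone (median -0.20, adjusted p 0.756). Rgs5 stood at -0.50 ± 0.14, Cspg4 at 0.47 ± 0.11 and Tagln at -0.36 ± 0.13. Tagln passed in only 4 of 13 fits that left out 1 array, with values from -0.46 to -0.25. With the liver score as covariate, 59 of 61 genes named as changed by diet in knockout mice passed. Tagln (-0.32 ± 0.14, limma adjusted p 0.101) and Rnase2a (-2.72 ± 1.09, limma adjusted p 0.0799) did not. Endothelial genes had 2 fallen of 11 (median -0.23, adjusted p 0.264), Robo4 at -0.87 ± 0.14 and Kdr at -0.75 ± 0.17. Each of these 3 lists passed camera's test of the interaction, with adjusted p of 0.000594, 7.49e-07 and 0.00979, but not with estimated correlation (0.481, 0.481 and 0.81). Camera did not pass the 16 lists not named here for knockout mice (adjusted p 0.125 to 0.778), of which fry passed adipose expansion (adjusted p 0.00578) and epididymis (adjusted p 0.00575).

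The diet effects of the genotypes were close. Across genes, which are not independent replicates, log2 changes in knockout and wild-type mice correlated at r of 0.918 (Spearman's rho 0.801). The slope of knockout on wild-type changes was 0.797 over the genes that passed in wild-type mice, and that of wild-type on knockout changes was 1.08 over those that passed in knockout mice, a different set. Of 6736 genes that passed in wild-type mice, 6542 moved the same way in knockout mice, or 97.1%. Both genotypes shared 2315 risen genes, against 481 for independent lists, and 2545 fallen genes, against 672, while 5 genes passed in opposite directions. Trem2, Adgre1, Casp1, Slc2a4 and Pck1 are among the shared genes. Tm4sf19 rose by 5.68 ± 0.37 in wild-type and 4.11 ± 0.35 in knockout mice, Trem2 by 3.89 ± 0.22 and 3.26 ± 0.21, while Orm3 stood at -3.52 ± 0.25 and -3.70 ± 0.24. None of the genes named here passed the interaction test.

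**Figure D3:**
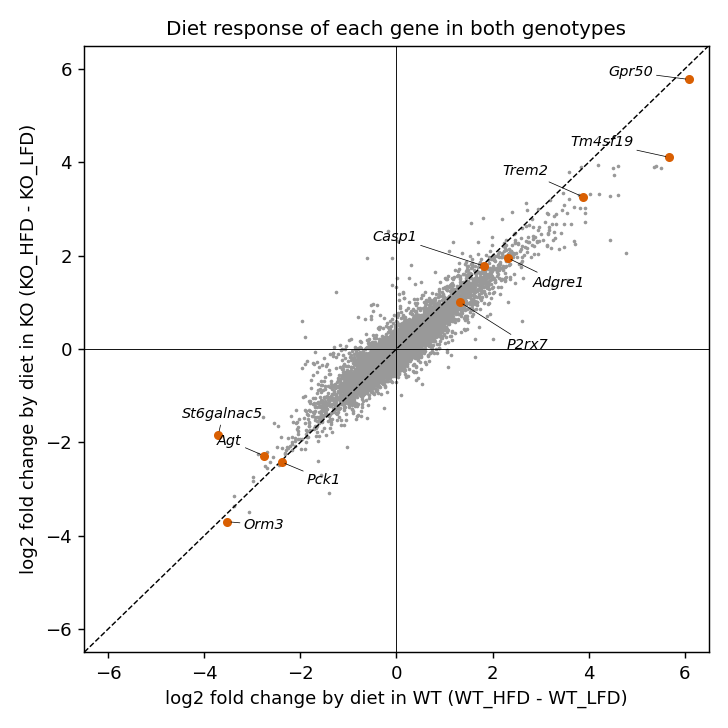
Log2 change of each gene by diet in wild-type mice (horizontal) and in knockout mice (vertical), with the line of equal change dashed. The changes correlate at r of 0.918, with Gpr50 and Tm4sf19 at the upper end and Orm3 at the lower end, and Tm4sf19 lies below the line.

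On chow, the genotypes were compared to ask what loss of P2X7 changes in lean fat. The knockout line had been backcrossed for 7 generations. A genotype difference on any chromosome, on either diet, thus cannot be told apart from donor sequence that may remain. P2rx7 itself did not differ (-0.16 ± 0.13), nor did Nlrp3 (0.11 ± 0.13, limma adjusted p 0.847), Pycard (0.17 ± 0.15, adjusted p 0.766), Casp1 (0.15 ± 0.14, adjusted p 0.779), Il1b (0.10 ± 0.17, adjusted p 0.902) or Il18 (-0.19 ± 0.11, adjusted p 0.622) past the threshold. Lrmda, a melanocyte differentiation gene, was lower in knockout mice by -2.42 ± 0.25 (adjusted p 0.00298), and Nipsnap2, a mitochondrial gene that lies 70 measured genes from P2rx7 on chromosome 5, by -0.72 ± 0.06 (adjusted p 0.000472). Lower too were the liver-rich genes Mup20 (-2.77 ± 0.47, adjusted p 0.046), Fabp1 (-2.38 ± 0.41, adjusted p 0.0485), Hamp, the iron hormone hepcidin (-1.48 ± 0.21, adjusted p 0.0222), and G6pc (-1.01 ± 0.17, adjusted p 0.0409), of which Mup20 has near-identical copies. The clock repressor Ciart (-1.09 ± 0.19), Nxpe5 (-0.92 ± 0.15), Capn6 (-0.88 ± 0.14) and A430033K04Rik (-0.76 ± 0.11) were also lower. Higher in knockout mice were the glycogen-binding Stbd1 (1.03 ± 0.14, adjusted p 0.022), the repressor Bcl6 (0.95 ± 0.15), the GABA receptor subunit Gabrq (0.86 ± 0.14) and the peptide hormone apelin (Apln, 0.83 ± 0.14). Disp2 (0.77 ± 0.11), Fam20c (0.72 ± 0.12), Wdfy1 (0.70 ± 0.12) and Rab4a (0.58 ± 0.09) were higher as well.

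In all, 9 genes were higher and 16 lower in knockout mice on chow, and 1810 had an unadjusted p under 0.05 where chance gives 941. Without replicate 1 of wild-type mice on chow 0 were higher and 4 lower, without replicate 2 of them 1 and 5, and without replicate 2 of wild-type mice on high-fat diet 14 and 30. Without replicate 1 of knockout mice on chow 0 were higher and 2 lower, but without their replicates 2 and 3 more were higher, 6 and 3, and 8 and 2. Without replicates 2, 3 and 4 of knockout mice on high-fat diet the counts were 3 and 6, 2 and 3, and 3 and 6. Lrmda and Nipsnap2 passed in each of the 13 fits that left out 1 array, Stbd1 in 11, Disp2 and A430033K04Rik in 8, Hamp in 7, Bcl6 and Capn6 in 6, Gabrq, G6pc and Rab4a in 5, Mup20, Fabp1 and Fam20c in 4, Apln, Nxpe5 and Wdfy1 in 3 and Ciart in 2. Stbd1 did not pass without replicate 1 of either genotype on chow, and its value ranged from 0.87 to 1.13. With the liver score as covariate, Nipsnap2 alone of the 18 named genes passed (-0.69, adjusted p 0.0491). Of the other 17, 8 were as large or larger with it, such as Ciart (-1.50 ± 0.25), Apln (1.11 ± 0.19), Nxpe5 (-1.11 ± 0.23) and A430033K04Rik (-0.87 ± 0.17), and Lrmda (-2.27 ± 0.40, adjusted p 0.134) and Stbd1 (1.02 ± 0.22) nearly so. These failed because the SE widened, by up to 1.59 times. Mup20 (-1.10 ± 0.41), Hamp (-0.77 ± 0.21), G6pc (-0.54 ± 0.19) and Capn6 (-0.73 ± 0.21) shrank by more than 1 SE, and so did Fabp1, which is part of the score. On chow the score ran from 6.68 to 7.42 in wild-type and from 5.76 to 5.82 in knockout mice, without overlap, so this fit separates genotype from the score poorly. The liver score was 6.99 ± 0.38 in wild-type and 5.78 ± 0.03 in knockout mice on chow (SD, n = 3 each; exact two-sided p 0.1, the smallest these numbers allow).

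No member of the gene lists passed over all genes on chow, while camera passed 5 lists upward and 2 downward. Interferon-stimulated genes had the smallest p, with all 20 members above 0 (median 0.36, camera adjusted p 1.72e-06, and 0.991 with estimated correlation), Oas2 at 0.67 ± 0.22 (adjusted p 0.339) and Oasl1 at 0.52 ± 0.18 (adjusted p 0.375). Without replicate 1 of knockout mice on chow the interferon median was 0.10. Oas2, Oas1a, Oasl1 and Oasl2 of this list lie within 100 measured genes of P2rx7 on chromosome 5. For them, an effect of P2X7 loss cannot be told apart from one of position. The unfolded protein response had 8 higher genes when adjusted over the list alone (median 0.18, adjusted p 8.75e-06, and 0.358 with estimated correlation), with Atf3 at 0.67 ± 0.16 (adjusted p 0.2) and Dnajb9 at 0.34 ± 0.08 (adjusted p 0.168). It was the 1 list that fry passed (adjusted p 0.03). Smooth muscle and pericyte genes were lower (median -0.30, adjusted p 0.000177, and 0.991 with estimated correlation; 1 lower when adjusted over the list alone), with Des at -0.41 ± 0.11. Lipid-associated macrophage genes had 3 higher when adjusted over the list alone (median 0.21, adjusted p 0.000682, and 0.991 with estimated correlation), with Plin2 at 0.24 ± 0.06 and Atp6v0d2 at 1.53 ± 0.46. Chemokines and cytokines had 2 higher when adjusted over the list alone (median 0.19, adjusted p 0.033, and 0.991 with estimated correlation), with Ccl2 at 0.84 ± 0.21 and Ccl7 at 0.69 ± 0.17, and de novo lipogenesis had 2 lower (median -0.13, adjusted p 0.0043, and 0.991 with estimated correlation), with Fads1 at -0.34 ± 0.10. Lysosomal genes moved little (median 0.09, adjusted p 0.0205, and 0.991 with estimated correlation). Lists that camera did not pass had list-alone calls too: 2 higher for adipose expansion, 1 higher each for collagens and cell division, and 1 lower each for neutrophils and skeletal muscle. With an estimated correlation 0 lists passed, and the inflammasome list did not pass in either test (median 0.09, camera, pointing down, adjusted p 0.986; 2 of 22 members with an unadjusted p under 0.05). Camera passed 12 lists without replicate 1 of wild-type mice, 3 without replicate 1 of knockout mice and 4 without replicate 3 of knockout mice, all on chow.

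On high-fat diet, the comparison asks whether P2X7 loss alters obese fat and its inflammasome. Nlrp3 (-0.17 ± 0.13, limma adjusted p 0.808), Pycard (-0.08 ± 0.14, adjusted p 0.937), Casp1 (0.10 ± 0.13, adjusted p 0.906), Il1b (-0.08 ± 0.16, adjusted p 0.937) and Il18 (-0.12 ± 0.10, adjusted p 0.843) did not differ past the threshold, and P2rx7 stood at -0.47 ± 0.12. Lrmda (-2.36 ± 0.24, adjusted p 0.00369), the TGF-beta family ligand Gdf3, known from macrophages of obese fat (-2.28 ± 0.29, adjusted p 0.00927), and Nipsnap2 (-0.42 ± 0.06, adjusted p 0.0163) were lower in knockout mice. Camk2b, a calcium-dependent kinase, was higher (0.88 ± 0.09, adjusted p 0.00412). Entpd4 (-0.64 ± 0.08, adjusted p 0.00772), Mid1 (-0.90 ± 0.10, adjusted p 0.00474), A430033K04Rik (-0.73 ± 0.10, adjusted p 0.0175) and Olfr734 (0.95 ± 0.15, adjusted p 0.0474) passed as well, but Entpd4, Mid1 and Olfr734 have close copies and their identity is uncertain. P2rx4, which lies 1 measured gene from P2rx7 on chromosome 5, stood at -0.52 ± 0.09 (adjusted p 0.0688), and Panx1 stood at -0.58 ± 0.16 (adjusted p 0.523). Without wild-type replicate 2 on high-fat diet both passed, P2rx4 at -0.63 (adjusted p 0.00387) and Panx1 at -0.84 (adjusted p 0.00235). P2rx4 also passed with array weights (-0.55, adjusted p 0.024) and with the liver score as covariate (-0.60, adjusted p 0.0272).

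These were all 8 genes that passed on high-fat diet, 2 higher and 6 lower, and 1394 had an unadjusted p under 0.05. With a replicate block, which in effect drops knockout replicate 4, 0 passed, and with only the groups compared in the fit 2. Wild-type replicate 2 weighed most: without it 63 genes were higher and 114 lower, 177 in all, and without wild-type replicate 3 the count was 14. Camk2b, Entpd4, Gdf3, Lrmda and Mid1 passed in each of the 13 fits that left out 1 array, Nipsnap2 in 10, A430033K04Rik in 9 and Olfr734 in 3. Nipsnap2 failed without wild-type replicate 3 and knockout replicates 2 and 4 on high-fat diet, with values from -0.45 to -0.40. Of the named genes all but Olfr734 (0.95 ± 0.17, adjusted p 0.0927, its SE wider) passed with the liver score as covariate. The inflammasome list had a median of -0.08 (camera adjusted p 0.501, with 2 of 22 members at an unadjusted p under 0.05), and without wild-type replicate 2 it was -0.16 (adjusted p 0.00152, and 0.347 with estimated correlation). With the liver score as covariate the median was also -0.16 and camera passed at its preset correlation, with no estimated correlation tried.

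No list member passed over all genes on high-fat diet, while 2 purinergic genes, 1 of glycolysis and hypoxia and 1 dendritic cell gene were lower when adjusted over the list alone. B cell genes were higher in knockout mice, all 11 above 0 (median 0.50, camera adjusted p 4.76e-06, and 0.699 with estimated correlation), with Igkc at 1.66 ± 0.49 (adjusted p 0.577) and Ighm at 1.01 ± 0.45 (adjusted p 0.661). The B cell mean was 6.98 on knockout replicate 2, and without that array the median was 0.16. Lysosomal genes were lower (median -0.11, adjusted p 0.000174, and 0.699 with estimated correlation; 1 lower when adjusted over the list alone), Ctsz by -0.24 ± 0.05 (adjusted p 0.278), and MHC class II genes had a median of -0.19 (adjusted p 0.0319, and 0.771 with estimated correlation). Upward were smooth muscle (0.21, adjusted p 0.000884, and 0.699 with estimated correlation), adipocyte identity (0.12, adjusted p 0.000711, and 0.771), branched-chain amino acid breakdown (0.11, adjusted p 0.000884, and 0.771) and adipose expansion (0.09, adjusted p 0.00161, and 0.699). Endothelial genes (0.16, adjusted p 0.00292, and 0.771 with estimated correlation), fatty acid oxidation (0.11, adjusted p 0.00492, and 0.773) and red blood cells (0.38, adjusted p 0.0319, and 0.699) were upward too. Of these 8 upward and 2 downward lists, 0 passed with an estimated correlation (adjusted p 0.699 to 0.773), and fry passed 0. Camera passed 4 lists without wild-type replicate 1, 17 without wild-type replicate 2 and 6 without knockout replicate 1.

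**Figure D4:**
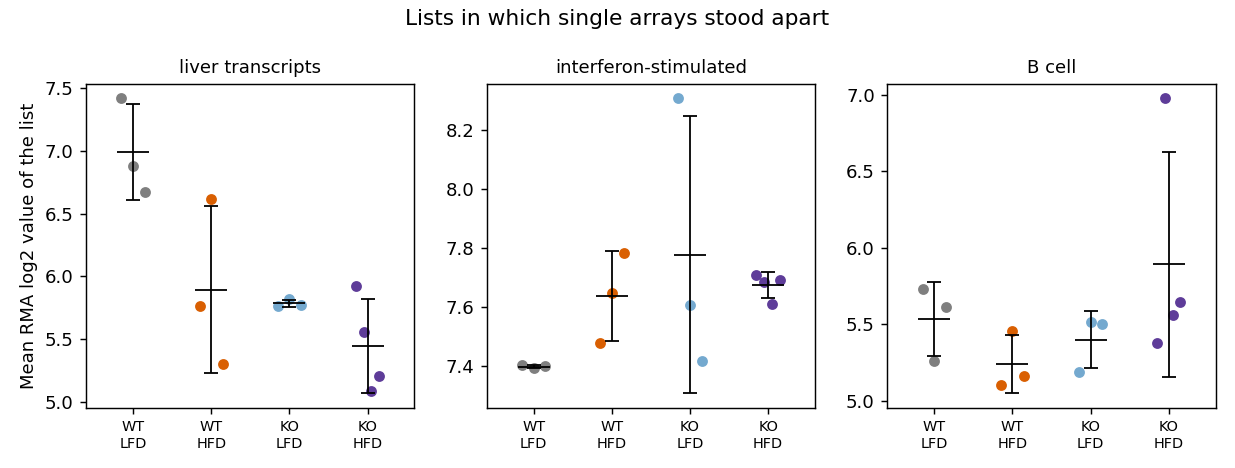
Mean log2 value of gene lists on each array by group. The interferon-stimulated mean is 8.31 on replicate 1 of knockout mice on chow and 7.39 to 7.78 elsewhere, and the B cell mean is 6.98 on replicate 2 of knockout mice on high-fat diet.

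Averaged over the diets, the genotype comparison gives the mean difference, so a gene that differs on a single diet can pass. Lrmda was lower in knockout mice by -2.39 ± 0.17 (limma adjusted p 3.98e-05), Nipsnap2 by -0.57 ± 0.04 (adjusted p 3.98e-05), Entpd4 by -0.62 ± 0.06 (adjusted p 0.000455) and Mid1 by -0.71 ± 0.07 (adjusted p 0.000881). Lrmda and Entpd4 lie on chromosome 14, where loss of P2X7 and remaining donor sequence cannot be told apart either. Camk2b was higher (0.68 ± 0.07, adjusted p 0.000881), as were the synaptic vesicle gene Sv2c (0.56 ± 0.08), the endosomal Rab4a (0.43 ± 0.06), Erdr1 (0.66 ± 0.10, with close copies) and Tnni3 (0.37 ± 0.06, adjusted p 0.0469). Hepcidin (Hamp, -1.03 ± 0.15) and A430033K04Rik (-0.75 ± 0.07) were lower. The inflammasome genes stayed short of the threshold, with Nlrp3 at -0.03 ± 0.09 (adjusted p 0.957), Pycard at 0.04 ± 0.11 (adjusted p 0.95), Casp1 at 0.12 ± 0.10 (adjusted p 0.822), Il1b at 0.01 ± 0.12 (adjusted p 0.994) and Il18 at -0.15 ± 0.08 (adjusted p 0.718), and P2rx7 stood at -0.31 ± 0.09 (adjusted p 0.385).

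In all, 9 genes were higher and 11 lower over both diets, and 1361 had an unadjusted p under 0.05; with arrays centred on their medians 7 were higher and 16 lower. The count was 11 without replicate 1 of wild-type mice on chow and 62 without replicate 2 of wild-type mice on high-fat diet. Lrmda, Nipsnap2, Entpd4, Mid1, Camk2b, Rab4a, Nxpe5 and A430033K04Rik passed in each of the 13 fits that left out 1 array, and Tnni3 in 1. Erdr1 and Sv2c each failed in at least 1 of those fits. Hamp failed without replicate 1 of wild-type or of knockout mice on chow (-1.13 to -0.88 over the arrays left out). With the liver score as covariate, 7 of the 15 genes named for this comparison passed, and 4 genes on chromosome 5 named next did not. Nor did Hamp (-0.55 ± 0.14, adjusted p 0.258), Erdr1 (0.56 ± 0.15, adjusted p 0.264) and Tnni3 (0.28 ± 0.09, adjusted p 0.355), which shrank by more than 1 SE, and Rab4a (0.38 ± 0.09, adjusted p 0.214), which moved by less and failed because its SE widened. Of all genes, 4 passed and were lower on both diets (Lrmda, Nipsnap2, Entpd4 and A430033K04Rik), where independent lists would share 0.0051. Camera passed 3 lists, all upward, interferon-stimulated genes (0.17, adjusted p 1.99e-05), the unfolded protein response (0.08, adjusted p 0.00283) and adipose expansion (0.13, adjusted p 0.00507), each at an adjusted p of 0.944 with estimated correlation, and fry passed 0. Without replicate 1 of knockout mice on chow the interferon median was 0.044 and camera did not pass (adjusted p 0.0782). Adjusted over the list alone, 1 gene each was higher for the unfolded protein response, adipose expansion, collagens and purinergic genes. Lower were 2 genes of de novo lipogenesis and 1 each of purinergic genes, the lysosome, thermogenic genes and neutrophils.

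Genes beside P2rx7 were then compared with the rest. Fisher's test treats genes as independent although they share the same arrays, so its p-values may be too small. Of 200 genes within 100 measured genes of P2rx7 on either side, 1 passed (Nipsnap2), against 19 of 18589 elsewhere (odds ratio 4.91, 95% interval 0.118 to 31.2, Fisher's exact p 0.193). Within 50 genes on either side 0 of 100 passed by limma (95% interval of the odds ratio 0 to 38.4, Fisher's exact p 1). An unadjusted p under 0.05, compared after these counts were seen, was more frequent near P2rx7 at both distances: 26 of 200 within 100 genes (odds ratio 1.94, 95% interval 1.23 to 2.95, Fisher's exact p 0.0035) and 17 of 100 within 50 (odds ratio 2.65, 95% interval 1.47 to 4.52, Fisher's exact p 0.000779). The interferon-stimulated genes Oas2, Oas1a, Oasl1 and Oasl2 lie within 100 genes, and whether they add to this excess was not tested. Within 200 genes on either side, a distance fixed beforehand as an alternative and singled out after its count was seen, 5 of 400 passed (odds ratio 15.5, 95% interval 4.38 to 45.1, Fisher's exact p 5.08e-05). Besides Nipsnap2 these were the mitochondrial fission gene Fis1 (-0.31 ± 0.05, adjusted p 0.0263, 146 genes away) and 3 genes at 191 to 193 genes away. Those were Cnpy4 (0.33 ± 0.05, adjusted p 0.0153), Mblac1 (-0.53 ± 0.08, adjusted p 0.0153) and Nxpe5 (-0.80 ± 0.11, adjusted p 0.0103). All 5 lay on the distal side of P2rx7, with A430033K04Rik just beyond, 201 genes away. Fis1 passed in 5 of the 13 fits that left out 1 array, Cnpy4 in 10 and Mblac1 in 12, failing without replicate 2 of knockout mice on chow (-0.57 to -0.48 over the arrays left out). With the liver score as covariate Nipsnap2 passed (adjusted p 0.0137). Cnpy4 (0.33 ± 0.08, adjusted p 0.196), Mblac1 (-0.58 ± 0.12, adjusted p 0.16) and Nxpe5 (-0.93 ± 0.16, adjusted p 0.0728) kept their size and failed because the SE widened, and Fis1 shrank as well (-0.24 ± 0.07, adjusted p 0.317). Chromosome 5 held 7 of the 20 genes, an excess singled out after it was seen (odds ratio 8.90, Fisher's exact p 8.03e-05, and 0.00161 adjusted over 20 chromosomes).

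**Figure D5:**
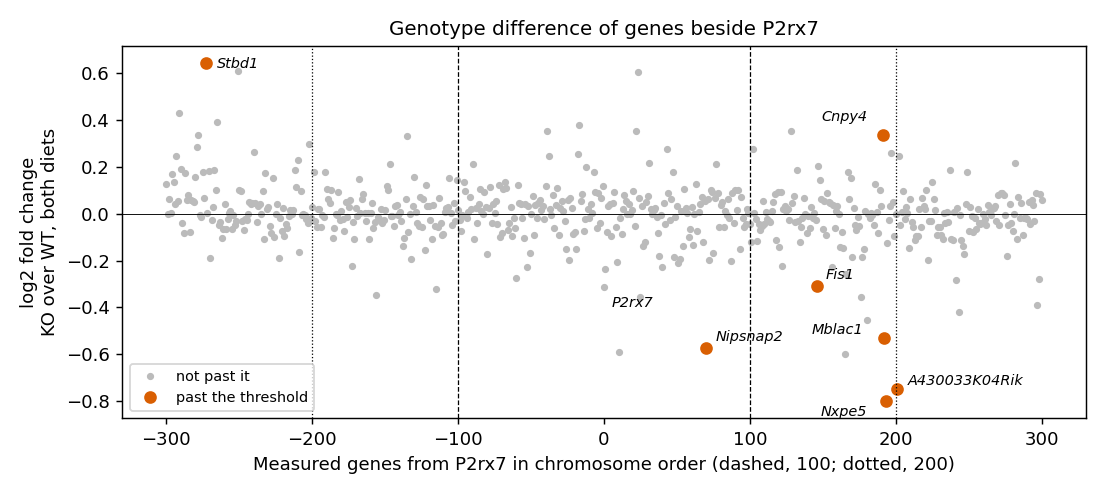
Log2 genotype difference averaged over diets for measured genes in their order around P2rx7 on chromosome 5, with genes past the threshold marked. Nipsnap2 lies 70 genes from P2rx7, and Cnpy4, Mblac1 and Nxpe5 lie 191 to 193 genes away.

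The interaction asks whether the diet acts differently when P2X7 is missing. By limma 0 genes passed (1829 with an unadjusted p under 0.05, smallest adjusted p 0.0783). Nlrp3 stood at -0.28 ± 0.18 (adjusted p 0.639), Pycard at -0.25 ± 0.21 (adjusted p 0.729), Casp1 at -0.05 ± 0.19 (adjusted p 0.955), Il1b at -0.18 ± 0.23 (adjusted p 0.833), Il18 at 0.07 ± 0.15 (adjusted p 0.92) and P2rx7 at -0.31 ± 0.18 (adjusted p 0.588). Values of list members short of the threshold included P2rx4 at -0.58 ± 0.13 (adjusted p 0.298), Panx1 at -0.72 ± 0.23 (adjusted p 0.375), Il33 at 0.79 ± 0.23 (adjusted p 0.354) and the monocyte attractants Ccl2 at -1.24 ± 0.29 (adjusted p 0.318) and Ccl7 at -0.95 ± 0.23 (adjusted p 0.318). Without replicate 2 of wild-type mice on high-fat diet, 21 genes had a positive and 85 a negative interaction, 106 in all, among them P2rx4 (-0.68, adjusted p 0.0276), Panx1 (-0.98, adjusted p 0.0127) and Atf3 (-1.12, adjusted p 0.0352). The count was 4 without replicate 3 of wild-type mice on high-fat diet, 2 without replicate 3 and 1 without replicate 2 of wild-type mice on chow. The inflammasome list had a median interaction of -0.10 (camera adjusted p 0.628, 5 of 22 members with an unadjusted p under 0.05), and -0.22 (adjusted p 0.0156, and 0.414 with estimated correlation) without replicate 2 of wild-type mice on high-fat diet.

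Camera passed 14 lists for the interaction, 8 upward and 6 downward, with no member past the threshold over all genes. Smooth muscle and pericyte genes had the smallest p (median 0.52, camera adjusted p 7.49e-07, and 0.481 with estimated correlation), with Rgs5 at 0.56 ± 0.20 and Cspg4 at 0.48 ± 0.17. Downward were the lysosome (-0.18, adjusted p 1.12e-05, and 0.481 with estimated correlation), with Hexa at -0.39 ± 0.11 and Ctsd at -0.30 ± 0.09, and lipid-associated macrophages (-0.32, adjusted p 0.000193, and 0.67 with estimated correlation; 1 member past the threshold when adjusted over the list alone), with Plin2 at -0.32 ± 0.08. The unfolded protein response (-0.26, adjusted p 0.000594, and 0.481 with estimated correlation) had 7 members past the threshold when adjusted over the list alone, with Atf3 at -0.96 ± 0.22 and Sdf2l1 at -0.98 ± 0.24. Interferon-stimulated genes (-0.33, adjusted p 0.00338, and 0.81 with estimated correlation), macrophages (-0.21, adjusted p 0.0229, and 0.81) and chemokines (-0.19, adjusted p 0.0497, and 0.752; 3 members past the threshold when adjusted over the list alone) were downward too. Without replicate 1 of knockout mice on chow the interferon median was -0.038 (camera adjusted p 0.705). B cell genes (0.57, adjusted p 0.000193, and 0.752 with estimated correlation; 1 member past the threshold when adjusted over the list alone) were upward, with Igkc at 2.69 ± 0.72. Without replicate 2 of knockout mice on high-fat diet the B cell median was 0.20 (camera adjusted p 0.00668, and 0.73 with estimated correlation). Upward too were branched-chain amino acid breakdown (0.14, adjusted p 0.00125), de novo lipogenesis (0.16, adjusted p 0.00631) and endothelial genes (0.20, adjusted p 0.00979), each at 0.81 with estimated correlation. Adipocyte identity (0.07, adjusted p 0.0229), fatty acid oxidation (0.08, adjusted p 0.0229) and oxidative phosphorylation (0.04, adjusted p 0.0433) were upward by small amounts, each again at 0.81. With an estimated correlation 0 lists passed (adjusted p 0.481 to 0.81 for these 14), and with fry 0. Among other lists, 1 gene each of purinergic, cell division, neutrophil and dendritic cell genes had a negative and 1 of skeletal muscle a positive interaction when adjusted over the list alone. Camera passed 8 lists without replicate 2 of wild-type mice on chow, 7 without replicate 1 of wild-type mice on high-fat diet, and 6 and 7 without replicate 1 of knockout mice on chow and on high-fat diet.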

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

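The tests of interferon-stimulated and B cell genes without 1 array, for genotype and for the interaction, were chosen after the results were seen, while the splits of the arrays were planned. Among knockout mice on high-fat diet, the 1 group with 4 arrays, 150 named genes and 38 list means were tested for an array far from the other 3. Of these 188 values 15 stood apart, where chance flags about 1 in 20, or 9.4. Replicate 1 gave 7 of them. On it Tm4sf19 read 10.89, Atp6v0d2 11.75, Entpd1 10.17, Aim2 8.03, Fat3 8.395 and the lipid-associated macrophage list 11.12, all below the other arrays, and Slc2a4 read 8.51, above them. Replicate 2 was high for Ighm (8.725), the B cell list (6.98) and the T cell list (6.18), and low for Fdft1 (9.16) and Asns (9.97). Replicate 3 was high for Agt (9.33), and replicate 4 was high for Msmo1 (9.96) and low for Bcat2 (9.38).

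Although 35 of 100 splits of the arrays gave as many, camera's test of the interaction passed 14 lists, none of them with an estimated correlation. Their median interaction values were 0.52 for smooth muscle and pericytes, 0.57 for B cells, 0.20 for endothelial cells, 0.16 for de novo lipogenesis, 0.14 for branched-chain amino acid breakdown, 0.079 for fatty acid oxidation, 0.068 for adipocyte identity and 0.041 for oxidative phosphorylation. They were -0.32 for lipid-associated macrophages, -0.33 for interferon-stimulated genes, -0.26 for the unfolded protein response, -0.21 for macrophages, -0.19 for chemokines and -0.18 for the lysosome. Without replicate 1 of knockout mice on chow the interferon value was -0.038 (camera adjusted p 0.705), and without replicate 2 of knockout mice on high-fat diet the B cell value was 0.20 (camera adjusted p 0.00668). Among probe sets not used in the tests of genes, 14 differed by genotype averaged over the diets, 13 of them with no gene and 1 with several.

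For B cell genes in knockout against wild-type mice on high-fat diet the median was 0.50, with 0 of 11 members past the threshold and a camera call lost with estimated correlation (adjusted p 0.699), and 1 array carried most of the shift. Without replicate 2 of knockout mice the median was 0.157, though camera with its preset correlation still passed (adjusted p 0.00584, and 0.785 with estimated correlation). Ighm read 8.725 on that array against 6.56 to 6.57 on the other 3, and the T cell mean was high there as well. Lymphoid tissue taken with that 1 sample may account for most of the shift. A genotype effect on B cells was neither shown nor excluded.

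For interferon-stimulated genes in knockout against wild-type mice on chow the median was 0.36, with 0 of 20 members past the threshold and an adjusted p of 0.991 with estimated correlation. Their mean on replicate 1 of knockout mice was 8.31, against 7.39 to 7.78 on every other array of the study. Without replicate 1 the median was 0.1025 and camera did not pass (adjusted p 0.2). That array also had the highest T cell mean on chow (5.76). Adam7, an epididymis gene looked up after the result was seen, read 4.90 there against 2.96 to 3.35 elsewhere, but the other 11 epididymis genes averaged 3.70 there and 3.54 to 3.75 elsewhere, which gives carried epididymis no support. An interferon response in that 1 sample is a candidate explanation for most of the shift, and a smaller genotype effect stays open. Oas2, Oas1a, Oasl1 and Oasl2 also lie within 100 measured genes of P2rx7, where genotype and position cannot be told apart.

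Other splits of the same arrays into groups of the same sizes, the real split included, were counted for each comparison. For diet in knockout mice 1 of 35 splits gave as many genes, so chance is unlikely but not excluded (6429 genes, highest other 3512). The same holds for genotype averaged over diets, with 1 of 100 splits (20 genes, highest other 7). Those 100 splits, also used for the interaction, were the real one and others drawn at random. For genotype on high-fat diet 2 of 35 gave as many, and chance cannot be excluded (8 genes, highest other 69). The split with 69, several times the real count, set replicate 2 of wild-type mice and replicates 1, 3 and 4 of knockout mice against the rest. It differs from the real split only in that replicate 2 of wild-type and replicate 2 of knockout mice change places. The real comparison gave 177 genes without replicate 2 of wild-type mice, and what the 69 genes reflect was not tested. For the interaction the splits decide nothing, since all 100 reach the 0 genes found (highest other 34). The 10 splits are too few for diet in wild-type mice (1 split as large, 6736 genes, highest other 1) and for genotype on chow (1 split as large, 25 genes, highest other 1). For counts of lists by camera, chance cannot be excluded for diet in knockout mice (11 of 35 splits, 16 lists, highest other 19), genotype on high-fat diet (22 of 35, 10 lists, highest other 21) or the interaction (35 of 100, 14 lists, highest other 21). Camera passed lists in all 34 other splits for diet in knockout mice and for genotype on high-fat diet, and in all 99 for the interaction. For lists the 10 splits are too few for diet in wild-type mice (3 splits as large, 18 lists, highest other 18) and genotype on chow (6 splits as large, 7 lists, highest other 13).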

How the results depend on the processing

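Of 29 settings 27 were planned, and the liver score as covariate and the removal of 2 arrays together (replicate 1 of knockout mice on chow and replicate 2 on high-fat diet) were chosen after seeing the data. Of 447 comparisons of a main result with its value under another setting, 386 kept direction and side of the threshold, or stayed within 1.5 times for counts. Of 6030 alternatives for 253 gene values 5682 did so, 337 lost the threshold in the same direction, 11 gained it and 0 reversed. The rest follow, and unless stated the cause was not tested. With a replicate block, which rests on shared numbers alone, 6 genes passed for genotype on chow, 0 on high-fat diet and 6 averaged over diets, and it changed no other count or list result beyond 1.5 times. No pairing by number was detected, although so few arrays could miss it: 6 of 18 same-number pairs had r over 0.1 (-0.30 to 0.22), and 4 of 13 arrays correlated best with their own number. Only knockout mice on high-fat diet had a replicate 4, so the block in effect drops that array. Without the intensity trend 2 genes passed for the interaction, and 1 with arrays centred on their median. With array weights 32 genes passed for genotype averaged over diets and 1 for the interaction, and the odds ratio near P2rx7 was 6.25 (p 0.0454). With only the groups compared in the fit 2 passed for genotype on high-fat diet. A minimum of 1.5-fold, a stricter demand by construction, left 3027 genes for diet in wild-type mice, 2474 in knockout mice and 10 for genotype averaged over diets. With an estimated correlation camera passed 0 lists for diet in wild-type mice, 0 in knockout mice, 0 for genotype on chow, 0 on high-fat diet and 0 for the interaction, since correlated members count for less; the inflammasome shifts, 0.61 in wild-type (adjusted p 0.343) and 0.51 in knockout mice (adjusted p 0.221), no longer passed. Fry passed 1 list for genotype on chow, 0 on high-fat diet and 0 for the interaction. With 200 genes on each side of P2rx7 the odds ratio was 15.5 (p 5.08e-05), and with 50 it was 0 (95% interval 0 to 38.4, p 1). Without the 2 arrays 3 genes and 3 lists passed for genotype on chow, 7 genes averaged over diets and 9 lists for the interaction. With the liver covariate 3685 genes passed for diet in wild-type mice, 5 genes for genotype on chow and 8 lists for the interaction. The inflammasome shift by genotype on high-fat diet was then -0.16 (camera adjusted p 0.0111 at the preset correlation, with no estimated correlation tried). The correlation of diet effects was 0.892 with this covariate (jackknife SE 0.0249). Leaving out each array in turn gave 5678 to 7039 genes for diet in wild-type mice, 5105 to 6652 in knockout mice, 2 to 44 for genotype on chow, 6 to 177 on high-fat diet, 11 to 62 averaged over diets and 0 to 106 for the interaction. It gave 17 to 19, 14 to 17, 3 to 12 and 4 to 17 lists in the first 4 of these and 6 to 18 for the interaction. The inflammasome shift ran from 0.48 to 0.67 for diet in wild-type mice, 0.39 to 0.62 in knockout mice, -0.16 to 0.022 for genotype on high-fat diet and -0.22 to -0.060 for the interaction, the P2rx7 genotype difference from -0.39 to -0.26, the diet correlation from 0.900 to 0.925 and the odds ratio near P2rx7 from 1.53 to 9.33. The highest count of genes in each comparison came without replicate 2 of wild-type mice on high-fat diet. Signal over background was not used here, and dim genes were tested only by leaving out those below the 25th percentile of mean level, which changed no main result beyond these limits.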

Other observations

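The clock and liver lists, the tests of probe mismatches, both tests of liver transcripts and the counts and splits by unadjusted p beside P2rx7 were chosen after the results were seen; the test of uncalled genes was written before its result was seen, for a distance singled out after its count. Clock genes changed with the diet. In wild-type mice the activators Arntl (1.60 ± 0.16) and Npas2 (1.93 ± 0.18) rose and the repressors Per3 (-1.57 ± 0.14), Per2 (-1.24 ± 0.18) and Ciart (-1.66 ± 0.19) fell. Of 14 measured clock genes 3 rose and 9 fell (camera adjusted p 0.0117, and 0.253 with estimated correlation). In knockout mice 3 rose and 7 fell (adjusted p 0.164), with Arntl at 0.74 ± 0.15, Npas2 at 1.00 ± 0.17, Per3 at -0.78 ± 0.13 and Ciart at -0.50 ± 0.18. The interaction was -0.86 for Arntl, -0.94 for Npas2 and 0.79 for Per3 (limma adjusted p 0.32 each) and 1.16 for Ciart (adjusted p 0.298), so no clock gene alone was shown to differ in its diet effect. As a list camera passed the interaction (median 0.28, adjusted p 0.00164, and 0.38 with estimated correlation) and genotype on chow (median -0.13, adjusted p 0.0162, and 0.547), so a difference between genotypes stays open. The hour at which tissue was taken is not given in the sources used here.

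Genes that differed by genotype averaged over diets lay in excess within 200 measured genes of P2rx7, 5 of 400 (Nipsnap2, Fis1, Cnpy4, Mblac1 and Nxpe5), but not within 100 (1 of 200, Fisher's exact p 0.193) or 50 (limma 0 of 100, Fisher's exact p 1). An unadjusted p under 0.05 was more frequent within 100 (26 of 200, odds ratio 1.94, Fisher's exact p 0.0035) and within 50 (17 of 100, odds ratio 2.65, Fisher's exact p 0.000779) as well. Interferon-stimulated genes that lie within 100 (Oas2, Oas1a, Oasl1 and Oasl2) were not left out of these counts. The 5 genes all lay on the distal side of P2rx7, and A430033K04Rik, which also passed, lay just beyond, 201 genes away. With the liver score as covariate only Nipsnap2 of the 5 passed (-0.55, adjusted p 0.0137), while Nxpe5 (from -0.80 ± 0.11 to -0.93 ± 0.16), Mblac1 (-0.53 ± 0.08 to -0.58 ± 0.12) and Cnpy4 (0.33 ± 0.05 to 0.33 ± 0.08) kept their size and lost their call to wider errors. Splits decide nothing about the count of 5, which 1 of 100, the real one, reached (highest other 0), because 95 of the other 99 splits called no gene anywhere. By the share of genes with an unadjusted p under 0.05, within 200 genes against elsewhere, 2 of 100 splits gave an odds ratio as large (1.87, highest other 1.90), but the distance was picked for its excess, so chance cannot be excluded. Donor chromosome left beside the targeted gene after 7 generations of backcrossing is a candidate explanation of the excess. Genes there that did not pass also had an unadjusted p under 0.05 more often, 45 of 395 against 1293 of 18374 (odds ratio 1.70, 95% interval 1.21 to 2.34, Fisher's exact p 0.00201). Fisher's test treats genes as independent although they share the same arrays, so its p-values may be too small and do not settle the cause. Probe mismatches with donor sequence could lower a reading, which stays open for the 4 genes that were lower because probe sequences were not used here. A mismatch that only lowers a reading would not account for the 1 that was higher, Cnpy4, but its probe sequences were not checked either. An effect of P2X7 itself on these genes was not separated from their position.

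Transcripts abundant in liver were higher in wild-type mice on chow than in the other groups. The list mean was 6.99 ± 0.38 in that group, 5.89 ± 0.67 in wild-type mice on high-fat diet, 5.78 ± 0.03 in knockout mice on chow (SD, n = 3 each) and 5.44 ± 0.37 in knockout mice on high-fat diet (SD, n = 4). Albumin (Alb) read 11.51, 10.93 and 10.80 on the 3 arrays of wild-type mice on chow and also 11.05 on replicate 2 of wild-type mice on high-fat diet. As deviations from group means, 87.5% of the other liver genes correlated with Alb at r over 0.5, as liver RNA carried into the samples may produce. That genotype lowers these genes stays open: wild-type minus knockout was 0.45 on high-fat diet (exact two-sided p 0.314) and 1.21 on chow (exact two-sided p 0.1, the smallest these numbers allow). Camera passed the list for genotype on both diets, with 2 of 25 genes above 0 on high-fat diet (adjusted p 0.000293, and 0.71 with estimated correlation) and 1 on chow (adjusted p 1.57e-28, and 0.237), but the list was written after this pattern was seen. Of 25 measured liver genes 14 fell with the diet in wild-type mice (camera adjusted p 8.81e-05, and 0.505 with estimated correlation), and several, such as Cyp2e1, are also expressed in fat. Among genes that differed on chow and are not in the score, Hamp moved from -1.48 ± 0.21 to -0.77 ± 0.21 with the liver score as covariate, which decides little because the score separated the genotypes there (6.68 to 7.42 in wild-type, 5.76 to 5.82 in knockout mice).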
